A study of Mus musculus with 16 samples.

How the data were processed

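RNA from whole testes of C57BL/6 mice was measured on Illumina bead arrays, on which each probe is a short oligonucleotide read as the brightness of many beads. The labels give 16 arrays in 8 groups, wild type and Emi2 knockout at P15, P21, P30 and P60 (postnatal days), with 2 arrays per group. The titles, the age labels and the series design give P15 for the youngest age, whereas the growth protocol gives p12, and P15 was used here. Nothing in the labels says that the 2 arrays of a group came from separate animals, so p-values measure only the spread between these arrays, which may be technical.

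A deposited table held the signal intensity of each probe with no background correction and no normalization, per the file headers. Beside each intensity the deposited table held a detection p-value from the scanner software, per the file headers. In the regular probes this column ran from 0 to 1 with rising signal, so it was read as 1 minus the p-value. In 816 rows it ran the other way, and these rows were treated as control probes and left out of the tests. A second table held log2 values normalized by the authors. These deposited log2 values were recomputed from the intensities by quantile normalization over all 26511 rows with no background correction, to within 0.00276 on the log2 scale. That table therefore has a known scale and no centring of genes, and its column medians lay at 7.39 for every array. The submitters' processing notes name limma without a version.

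The intensities were corrected for background with the normexp model, with the background mean and spread estimated from the detection p-values of the regular probes. An offset of 16 was added, and the log2 values were quantile normalized between arrays. Of 25695 regular probes, 17362 had a detection p under 0.05 on at least 2 arrays. The gene table gave 1 symbol for 24277 regular probes, no symbol for 1418 and several for 0. Of those symbols, 22986 were updated through their gene number in the RefSeq gene table of GRCm38.p6, and 1291 were kept. The probe with the highest mean per symbol was kept, which left 13491 tested probes and set aside 3871. A linear model over the 8 group means was fitted with limma 3.58.1 in R 4.3.3 with moderated variances (8 residual and 5.52 prior degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05, and a second count also asked for a log2 change of at least 1. Every adjusted p given for a probe is from this limma model. The number of arrays limits the precision. On simulated arrays with 100 probes shifted by a log2 change of 2 among 13491, the model found 97 at P15, 92 at P21, 94 at P30 and 93 at P60. With a log2 change of 1 it found 36, 24, 34 and 31 of 100. Changes of that size were mostly missed on these simulated arrays. The simulated spread was the same at every age, so these figures do not rank the ages. Few probes were shifted, which makes the adjusted threshold stricter than where many differ. At P60, 6088 probes passed and 3818 of them had a log2 change of at least 1 in size. The simulation therefore does not give the share missed there.

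The gene names were not borne out by the values. Probes named for ribosomal proteins, which every cell makes in large amounts, were detected on both P60 wild-type arrays in 29 of 61 cases (47.5%, exact Clopper-Pearson 95% interval 34.6% to 60.7%). Probes named for olfactory receptors were detected in 562 of 1154 cases (48.7%), and all regular probes in 47.8%. The probe named Prm1, a protamine of elongating spermatids, had a log2 signal of 10.65 ± 0.14 (SD, n = 2) in wild type at P15, before spermatids form, and 10.22 ± 0.06 (SD, n = 2) at P60. The probe named Tnp1, a transition protein of the same cells, was detected on 0 of 2 P60 wild-type arrays. Levels of 9290 pairs of probes that share a symbol had a correlation of 0.192 across pairs, against -0.00958 for random pairs, and probes are not independent replicates.

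After this was seen, other row orders were looked for. Cyclic shifts of the rows, 77889 in all, were scored by the mean level of the ribosomal protein probes. The gene table was also sorted in 18 ways by 9 keys, scored by the correlation of neighbouring levels. Those sorts kept each level with its own probe. They therefore paired no name with another level, and asked only whether neighbours had similar levels. The highest ribosomal mean over all shifts was 9.01, the maximum of a search over that many orders, against 8.21 for the same rows as deposited, and the largest neighbour correlation was 0.02 in size. Short row shifts scored by probes that share a symbol, and running means of the sorted levels, were also looked at and gave no order. No order was adopted, no gene was inferred from values, and whether the fault lies in the tables or in the gene table is not known.

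Results are therefore given by probe identifier, with no gene name and no theme. If the deposited tables join identifiers and values wrongly, the identifiers do not tell which sequence was measured either. They serve here only as row labels. Before the data were examined, the tests, the alternatives, 15 gene lists and a rule for named genes had been set. That rule took the 6 largest rises and falls per genotype comparison among probes past the threshold whose knockout arrays lay outside the wild-type range, examples from each list, and the targeted gene and its paralog. Because names did not hold, it was applied to probe identifiers and shortened to the 2 largest rises and falls, and for time steps and changes of genotype effect to the largest rise and fall, without the condition on array ranges. List examples were not given. The choice of 1 probe per symbol was kept as set, although it rests on those names and here only thins the probes. Counts over all 17362 probes, also set beforehand as an alternative, are given beside it in the closing section. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and are reported only as a further check of the names.

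Where a probe had a detection p of 0.05 or more on both arrays of a group, its fold is given as "at least". The bright group's mean was then set against the mean, over the dim group's arrays, of the higher of the dim probe's value and the lowest value among detected probes. The alternatives were no background correction, scaling of each array to a common 75th percentile, the deposited log2 values, no filter, a stricter filter (detection p under 0.01 on both arrays of a group), all probes singly, the replicate number as a block, each array left out in turn, the 4 arrays of an age alone, and the estimated correlation for gene lists. A slide block was not run because no slide code is used here. Background parameters from the control rows' own signals were added after seeing the data.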

Results

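Transcript levels in whole testis were measured in wild-type and Emi2 knockout mice at 4 ages, P15, P21, P30 and P60, with 2 arrays per group and 16 in all. Emi2 is an inhibitor of the anaphase-promoting complex, the ubiquitin ligase that drives the exit of a dividing cell from mitosis or a meiotic division. The title of the series places it in mouse spermatogenesis. Between 13170 and 14636 regular probes were detected per array, and median signals before normalization lay between 132.5 and 213.7. Replicate arrays had correlations across probes of 0.974 to 0.988, and their root-mean-square (RMS) log2 difference was 0.375 to 0.561. The gene names attached to the probes did not go with the measured levels, so all results are for probes and name no gene as changed. Probe identifiers are used as row labels, since they too may be joined to the wrong values.

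**Figure D1:**
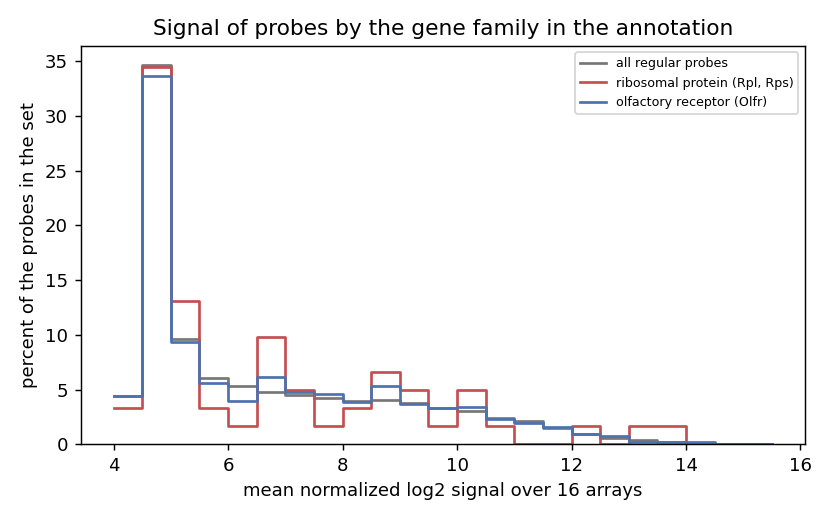
Distribution of the mean normalized log2 signal over 16 arrays (x axis) as the percent of probes in each set (y axis), for all regular probes, for probes named as ribosomal proteins and for probes named as olfactory receptors. The median log2 signals were 5.61, 5.41 and 5.71, so the named families were not separated from each other.

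The targeted gene should come first, because it checks the labels. The probe named Fbxo43, the gene symbol of Emi2, had a log2 signal of 11 ± 0.20 (SD, n = 2) in knockout and 11.01 ± 0.21 (SD, n = 2) in wild type at P15. At P21 it was 9.29 ± 0.39 and 9.31 ± 0.45 (SD, n = 2 each). At P30 it was 8.73 ± 0.30 in knockout and 10.25 ± 0.10 in wild type (SD, n = 2 each), a log2 difference of -1.52 (limma adjusted p = 0.000749). At P60 it was 9.31 ± 0.07 and 10.40 ± 0.06 (SD, n = 2 each), a log2 difference of -1.10 (limma adjusted p = 0.00455). Since the name is not borne out, these values identify no transcript and check no genotype label. The probe named for its paralog Fbxo5 was detected on 0 of 2 arrays in every group.

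The first comparison asked how knockout testis differed from wild type at each age. At P15 few probes differed, as 2 of 13491 tested probes were higher in knockout and 0 lower (limma), with 234 at an unadjusted p under 0.05. ILMN_2736521 was not well above background in wild type and was at least 6.51-fold higher in knockout (adjusted p = 0.0124). ILMN_1234281 was at least 3.55-fold higher (adjusted p = 0.00129), again with wild type not well above background. The count was 0 without background correction and with the deposited log2 values, and 1 without P15 Emi2 knockout replicate 1 or without P15 wild type replicate 2.

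At P21, 613 probes were lower and 114 higher in knockout, and most of the lower probes differed strongly. Of those lower, 583 had a fitted log2 change of at least 1 in size and 102 a fitted change of at least 16-fold, whereas of those higher 72 and 0 did. ILMN_3152486 had a log2 signal of 12.59 ± 0.10 in wild type and was not well above background in knockout, which made it at least 178-fold lower (adjusted p = 9.78e-10). ILMN_1225334 was 13.03 ± 0.42 in wild type and 6.13 ± 0.56 in knockout (SD, n = 2 each; limma adjusted p = 3.98e-09). ILMN_1212921 was not well above background in wild type and at least 6.94-fold higher in knockout (adjusted p = 3.87e-07). ILMN_2740869, detected on 1 of 2 wild-type arrays, was 5.10 ± 0.14 in wild type and 8.49 ± 0.94 in knockout (SD, n = 2 each; limma adjusted p = 1.6e-05). The count past the threshold was 727, and it was 443 without P21 wild type replicate 1 (45 higher and 398 lower) and 409 when only the 4 P21 arrays were fitted. Without P21 Emi2 knockout replicate 1, 47 were higher and 655 lower, and without P21 Emi2 knockout replicate 2, 162 and 488. With background parameters from the control rows it was 169, of which 73 were higher and 96 lower. Without background correction 197 were higher and 534 lower, and with the replicate block 188 and 741.

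At P30, 1434 probes were lower and 1924 higher in knockout. The falls were the larger changes, with 365 probes lower and 1 higher by at least 16-fold in the fitted values. ILMN_2703566 had a log2 signal of 15.05 ± 0.03 in wild type and 5.59 ± 1.13 in knockout, where it was detected on 1 of 2 arrays (SD, n = 2 each; limma adjusted p = 2.17e-07). ILMN_2657376 was 14.99 ± 0.08 in wild type and 6.04 ± 0.04 in knockout (SD, n = 2 each; limma adjusted p = 3.28e-10). ILMN_1212921 was again not well above background in wild type and at least 51.3-fold higher in knockout (adjusted p = 1.54e-10). ILMN_3036678 rose from 6.46 ± 0.16 in wild type to 10.32 ± 0.18 in knockout (SD, n = 2 each; limma adjusted p = 6.05e-08). The median log2 difference over all tested probes was 0.277, and the counts do not subtract this shift. It was 0.223 with 75th percentile scaling, 0.13 without background correction, 0.121 without a filter, 0.337 with the stricter filter and 0.00142 with background parameters from the control rows. That last setting shrank the medians of comparisons between ages too, from -0.198 to -0.000852 for wild type P21 minus P15. Its small value is therefore not particular to genotype. The count of 3358 was 1697 without P30 wild type replicate 2 (642 higher and 1055 lower) and 2106 without P30 Emi2 knockout replicate 1 (912 and 1194). It was 2213 without P30 Emi2 knockout replicate 2 (1055 higher and 1158 lower) and 2041 with only the 4 P30 arrays. Whether more probes were higher or lower at P30 therefore depended on single arrays, and on whether a log2 change of at least 1 was asked for.

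At P60 the count was highest, with 2028 probes lower and 4060 higher in knockout, together 45.1% of those tested. The direct limma test of a change from P30 to P60 found 0 of 13491 probes, so a wider difference than at P30 was not shown. Again 433 were lower and 7 higher by at least 16-fold in the fitted values. With a log2 change of at least 1 also asked for, 1654 were lower and 2164 higher. ILMN_2726850 was 14.03 ± 0.15 in wild type (SD, n = 2) and not well above background in knockout, at least 432-fold lower (limma adjusted p = 1.19e-11). ILMN_2613841 was 13.95 ± 0.02 in wild type (SD, n = 2) and at least 409-fold lower in knockout (limma adjusted p = 1.19e-11). ILMN_1212921 was at least 51.1-fold higher in knockout (adjusted p = 1.5e-10), with wild type not well above background. ILMN_2847332 was 6.20 ± 0.69 in wild type and 10.97 ± 0.14 in knockout (SD, n = 2 each; limma adjusted p = 4.03e-06). Without P60 wild type replicate 2, 2535 were higher and 1673 lower, and with background parameters from the control rows 2602 and 1908. The median log2 difference over all tested probes was 0.315, and 0.187 with 75th percentile scaling, under which 3481 probes were higher and 2091 lower. It was 0.144 without background correction, 0.116 without a filter and 0.415 with the stricter filter. Its size thus depended on the background treatment and the filter. With background parameters from the control rows it was 0.00149, but that setting shrank the medians of comparisons between ages too.

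**Figure D2:**
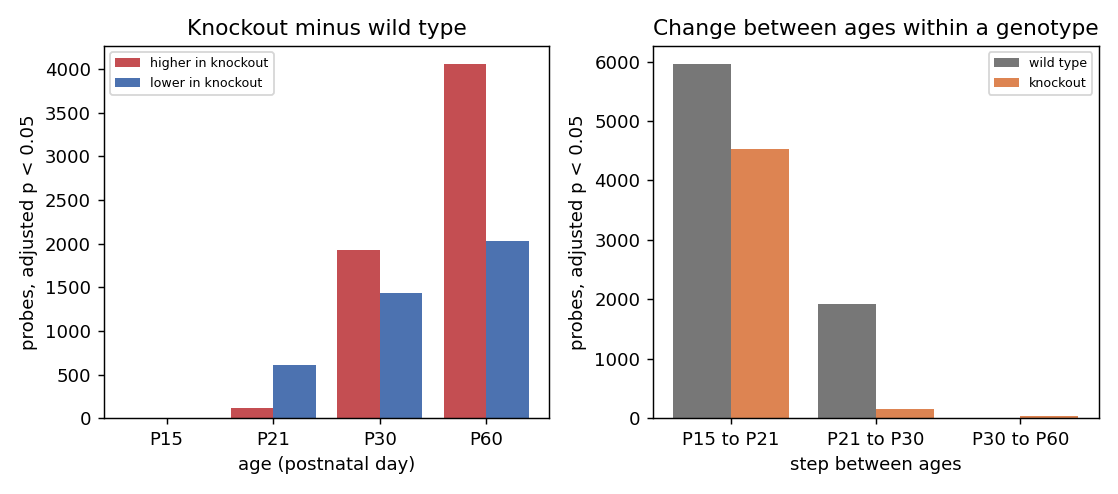
Left, number of probes (y axis) past an adjusted p of 0.05 that were higher or lower in knockout at each age (x axis). Right, number of probes that changed between successive ages within wild type and within knockout, where the step from P21 to P30 had 1924 probes in wild type and 153 in knockout.

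From P21 on, probes that differed at an age mostly differed the same way at the next, in comparisons whose group means share no array. Of the 2 probes higher at P15, 0 were higher at P21 or P30 and 1 at P60. Of the 613 probes lower at P21, 576 were also lower at P30 and 585 at P60, against 65.2 and 92.1 for independent lists. Of the 1434 lower at P30, 1366 were lower at P60, against 216 for independent lists. Of the 1924 higher at P30, 1554 were higher at P60, against 579. In the opposite direction lay 1 of the 1434 and 1 of the 1924. The tests of a probe at each age used the same spread, estimated from all arrays, which favours overlap in either direction. The figures for independent lists leave this out and are too low a baseline.

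The second comparison followed each genotype over age. Between P15 and P21, 2388 probes rose and 3577 fell in wild type, and 1956 rose and 2574 fell in knockout. Of these, 1491 rose and 2130 fell in both, against 346 and 682 for independent lists. Those figures leave out that both tests of a probe used the same spread, which favours overlap. In wild type ILMN_2999755, detected on 1 of 2 arrays at P15, rose from a mean log2 signal of 5.04 to 14.09 (limma adjusted p = 5.77e-10). In knockout the same probe was not well above background at P15 and rose at least 315-fold (adjusted p = 1.45e-09). ILMN_3149058 fell by 4.65 on the log2 scale in wild type (limma adjusted p = 2.24e-08), and ILMN_3135991 fell at least 22.9-fold in knockout (adjusted p = 0.00833), to a level not well above background. The wild-type count of 5965 was 3501 without P21 wild type replicate 1, where 1687 rose and 1814 fell. Without P15 wild type replicate 1, 1847 rose and 2208 fell, and without P15 wild type replicate 2, 1918 and 2371. With background parameters from the control rows 1361 rose and 3559 fell in wild type, and 1260 and 2860 in knockout. The knockout count of 4530 was 2090 without P21 Emi2 knockout replicate 1, where 1149 rose and 941 fell, and 2796 without P15 Emi2 knockout replicate 1, where 1389 rose and 1407 fell.

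Between P21 and P30 wild-type testis went on changing, with 1011 probes rising and 913 falling, while 100 rose and 53 fell in knockout. ILMN_2949877 rose at least 126-fold in wild type (adjusted p = 6.16e-08), from a level not well above background, and ILMN_2980110 fell at least 9.93-fold to such a level (adjusted p = 0.0347). In knockout ILMN_2759669 rose by a log2 change of 5.21 (limma adjusted p = 0.0331). ILMN_2618597 fell from a mean log2 signal of 8.30 to 5.38, detected on 1 of 2 arrays at P30 (limma adjusted p = 0.00779). The wild-type count of 1924 was 737 without P21 wild type replicate 2 (681 rising and 56 falling) and 707 without P30 wild type replicate 2 (626 and 81). It was 953 with background parameters from the control rows (675 rising and 278 falling). Without background correction 1018 rose and 1267 fell, and with the replicate block 1220 and 1605. Which direction had more probes at this step was therefore not settled, nor was the number of falling probes. The knockout count of 153 ranged from 41 without P21 Emi2 knockout replicate 2 (34 rising and 7 falling) to 653 without P21 Emi2 knockout replicate 1 (408 and 245), and was 444 with the replicate block. The size of the knockout step at this interval is therefore poorly fixed by these arrays.

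Between P30 and P60, 4 probes rose and 8 fell in wild type, and 26 rose and 9 fell in knockout. ILMN_1213615 rose in both, by a log2 change of 3.73 in wild type (limma adjusted p = 0.043) and 4.36 in knockout (limma adjusted p = 0.0192). ILMN_2736521 fell in wild type from a mean log2 signal of 8.19 to 5.25, detected on 1 of 2 arrays at P60 (limma adjusted p = 0.0254), and ILMN_2604486 fell by 2.23 in knockout (limma adjusted p = 0.0468). The wild-type count of 12 was 0 with 75th percentile scaling and 359 without P30 wild type replicate 2 (306 rising and 53 falling), and the knockout count of 35 was 3 with no filter on dim probes and 5 without P15 wild type replicate 1.

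The third comparison tested whether the genotype difference itself changed between ages. From P15 to P21 it became more negative for 400 probes and more positive for 29. ILMN_3152486 had the largest negative fitted change (limma adjusted p = 8.46e-08) and ILMN_2740869 the largest positive (limma adjusted p = 0.000576). Each was not well above background in both P15 groups, so no size is given. From P21 to P30 it became more negative for 581 probes and more positive for 51. ILMN_2949877 had the largest negative change (limma adjusted p = 2.9e-06), with no size given because it was detected in 1 of the 4 groups compared, P30 wild type. ILMN_3139952 changed by 4.21 (limma adjusted p = 0.0466). Of the 1011 probes that rose in wild type at that step, 566 rose less or fell in knockout by this test. For 15 of the 913 that fell in wild type the difference became more positive. The wild-type step and this test share the same wild-type arrays, which favours such overlaps, so these counts are not independent support. From P30 to P60 no probe passed in the limma test (0 of 13491), with 1037 at an unadjusted p under 0.05, and 98 passed without P30 wild type replicate 2. With background parameters from the control rows the counts of the earlier steps were 9 and 86. Leaving out each array in turn, the probes with a more positive difference ranged from 12 to 50 at the first step. At the second step the count of 51 was 31 without P30 wild type replicate 2, 93 without background correction and 106 with the replicate block. Without P21 Emi2 knockout replicate 2 it nearly doubled, to 16.7% of the 605 probes that passed.

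The last planned comparison set the genotype difference against wild-type development, with group means from arrays that the genotype difference did not use. Of the 1434 probes lower in knockout at P30, 1282 (89.4%) rose in wild type from P15 to P60, against 351 for independent lists, and 21 fell. Of the 1924 higher at P30, 1269 (66.0%) fell in wild type from P15 to P60, against 804, and 139 rose. Of the 2028 lower at P60, 1521 (75%) rose from P15 to P30 in wild type, against 459. Of the 4060 higher at P60, 2793 (68.8%) fell from P15 to P30, against 1591. Probes are not independent, so no p-value is given for these counts. Both tests of a probe also used the same spread, estimated from all arrays, which favours overlap in either direction. The figures for independent lists leave this out and are too low a baseline. Even so, the 21 probes lower at P30 that fell were below the 599 for independent lists. The 139 higher at P30 that rose were below 471. At P30 the 2551 probes that went opposite ways were 1356 without P30 wild type replicate 2 and 1658 without P30 Emi2 knockout replicate 2.

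Whole profiles followed the same course. The P15 groups differed by a mean RMS log2 difference of 0.362, below the lowest difference between replicates, 0.375. P60 knockout arrays differed from P30 knockout arrays by 0.521, from P21 knockout arrays by 0.728, from P21 wild-type arrays by 0.883, from P30 wild-type arrays by 1.338 and from P60 wild-type arrays by 1.508. P30 and P60 wild-type arrays differed by 0.535.

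**Figure D3:**
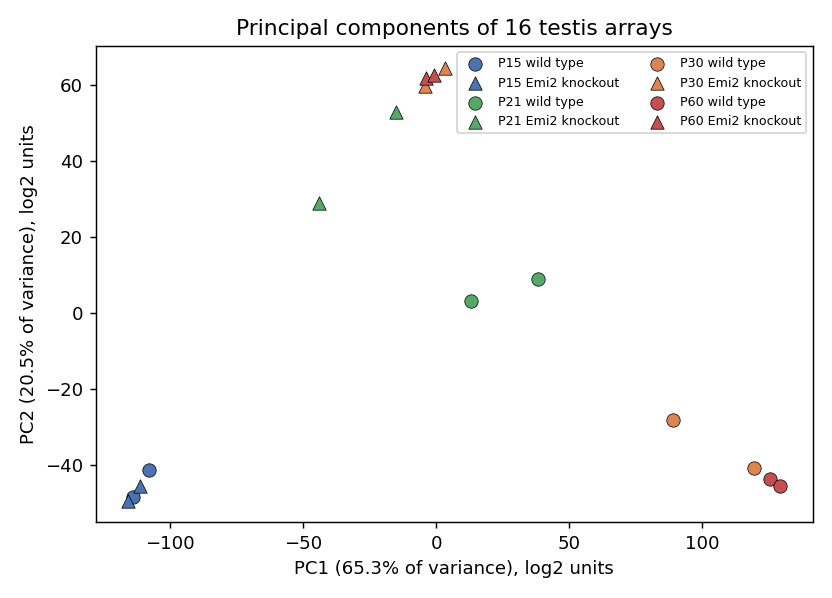
Principal components of 16 arrays over 13491 probes, with PC1 (65.3% of the variance) on the x axis and PC2 (20.5%) on the y axis, circles for wild type and triangles for knockout, coloured by age. The 4 knockout arrays of P30 and P60 sit together between -4.31 and 3.35 on PC1, and the 4 wild-type arrays of those ages lie between 88.8 and 129 on PC1.

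The gene lists set beforehand gave a further check of the names. Together they had 164 tested probes, of which 0 passed at P15, 5 (3.05%) at P21, 36 (22.0%) at P30 and 70 (42.7%) at P60, where all tested probes passed in 0.0148%, 5.39%, 24.9% and 45.1%. Adjusted over the list alone, the counts summed to 0, 8, 37 and 70. At P60 the probes named for round spermatids passed in 6 of 13 cases and those for elongating spermatids in 5 of 12. The count was 7 of 16 for pachytene and later spermatocytes, 7 of 14 for early meiotic prophase and 4 of 9 for spermatogonia. Among the somatic lists it was 6 of 10 for Sertoli cells, 6 of 11 for Leydig cells and steroid synthesis, 6 of 14 for peritubular and interstitial stroma, 5 of 12 for macrophages and other leukocytes and 5 of 9 for endothelium. It was 0 of 2 for red blood cells, 2 of 8 for epididymis, 3 of 11 for regulators of G2/M and meiotic division, 4 of 10 for the anaphase-promoting complex and 4 of 13 for p53 targets and cell death. With camera, 0 of 60 list tests passed with the preset correlation and 0 with an estimated correlation. The lowest unadjusted p was 0.0141, for endothelium at P60 (adjusted p = 0.847, and adjusted p = 0.898 with an estimated correlation). In fry, which asks only whether a list moves on balance one way, 18 of 60 passed, and that test does not compare a list with other probes.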

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

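The genotype counts, the changes in genotype effect and the 75th percentile scaling were set before the data were seen. The tests of array brightness, of distances between profiles, of names and of control rows were chosen after the results were seen.

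The genotype difference changed with age for 429 probes between P15 and P21 and for 632 between P21 and P30, by the test of the difference itself. With background parameters from the control rows, added after the data were seen, these counts were 9 and 86, so how many probes changed depended on the background treatment. Between P30 and P60 the test found 0 of 13491, with 1037 at an unadjusted p under 0.05. The count of probes that differed by genotype was 2 at P15, 727 at P21, 3358 at P30 and 6088 at P60, and such counts do not themselves test a change. A difference in array brightness between genotypes is argued against, because the log2 difference of median raw signal was 0.44 at P15, with 2 probes past the threshold, and 0.16 at P60. The quantile normalization as the whole cause is argued against by 5572 probes at P60 after 75th percentile scaling, of which 5465 were also past the threshold in the same direction with quantile normalization. Scaling also brings arrays to a common level, and the median log2 difference at P60 was still 0.187 under it. It therefore cannot decide whether either normalization lifted the many smaller rises. A delay in development made up by P60 is argued against too. The largest RMS log2 difference of a P60 knockout array from a P21 wild-type array was 0.916, below the smallest from a P30 wild-type array, 1.217. A lasting arrest or a lower share of later germ cells in knockout testis is the biological reading the design offers, and it may hold, but no cell type could be checked because the names do not hold.

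The second pattern is that gene names mostly did not go with levels. Noisy hybridisation is argued against by the lowest replicate correlation, 0.974. A wrong join of identifiers and values, or a wrong gene table, would give shares like the 47.5% of ribosomal protein probes detected in P60 wild type, beside 47.8% of all probes. Those shares raised this explanation, so they do not test it. Which of these tables is at fault stays open. The correlation of 0.192 between probes of a shared symbol was above the -0.00958 of random pairs, so some tie may remain. How many symbols carry it was not tested. No biological explanation was tested.

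Among the 816 control rows, which enter no comparison, limma with quantile normalized values found 6 past the threshold between genotypes at P30, 4 of them higher in knockout, and 9 at P60, 6 of them higher. At P15 and P21 it found 0. At an unadjusted p under 0.05 in the same test, there were 40, 32, 39 and 51 of the 816 rows from P15 to P60.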

How the results depend on the processing

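Background parameters from the control rows' own signals were added after seeing the data. All other alternatives were planned. Besides leaving out arrays, 110 of 133 values lay within 1.5 times the main count and 23 did not, and the cause was not tested. These values are not separate checks. The deposited values are nearly the same setting as no background correction, and gene list calls, 0 in every setting, count as within. The call at P15 (2) was 0 without background correction, 0 with the deposited values, 1 without a filter, 1 with the 4 arrays of that age and 0 with the control rows' parameters. With the 4 arrays of an age alone, P21 had 409 and P30 2041. The wild-type step from P30 to P60 (12) was 1 without background correction, 0 with 75th percentile scaling, 1 with the deposited values and 53 with the control rows' parameters. The knockout step from P30 to P60 (35) was 15 without background correction, 15 with the deposited values, 3 without a filter, 55 with all probes tested singly and 69 with the replicate block. The knockout step from P21 to P30 (153) was 444 with the replicate block. With the control rows' parameters, P21 had 169, the changes in genotype effect 9, 86 and 7, the wild-type step from P21 to P30 953 and the knockout one 97. Those parameters also shrank the median log2 change of comparisons between ages, from -0.198 to -0.000852 for wild type P21 minus P15.

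With all probes tested singly, as the names used to thin them did not hold, the genotype counts were 2, 893, 4082 and 7506 from P15 to P60. Arrays of one replicate number deviated together with correlations of 0.0542, 0.488, 0.140 and 0.164 from P15 to P60. The numbers were not taken as pairs, and the block moved no other total by over 1.5 times. Of their counts by direction it moved the probes rising in wild type from P30 to P60 from 4 to 7, those higher at P21 from 114 to 188, those falling in wild type from P21 to P30 from 913 to 1605, and those with a more positive genotype effect from P21 to P30 from 51 to 106.

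Leaving out each array in turn, the lone array of its group was assumed to vary like the others. The genotype counts ranged from 1 to 2 at P15, 443 to 785 at P21, 1697 to 3648 at P30 and 4208 to 6357 at P60. Changes in genotype effect ranged from 305 to 483, 459 to 786 and 0 to 98. Wild-type steps ranged from 3501 to 6186, 707 to 2467 and 0 to 359, and knockout steps from 2090 to 4961, 41 to 653 and 5 to 42. Gene list calls were 0 throughout. The overlap with development ranged from 1356 to 2753 at P30 and 3108 to 4477 at P60. Signal near background limits the dim probes, since 8333 of 25695 were not detected on at least 2 arrays.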

Other observations

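The probe groups here, the test against every wild-type age and the look at replicates were chosen after the data were seen, whereas the genotype test at P60 and the 75th percentile scaling were set before. Tested probes were grouped by when both wild-type arrays of an age first detected them (detection p under 0.05). A group of 130 probes was detected on neither wild-type array at P15 and P21 and on both at P30. On P60 wild-type arrays, not used to define the group, 105 (80.8%) were detected on both. In knockout 10 (7.69%) were detected on both arrays at P30 and 4 (3.08%) at P60. Their mean log2 signal at P60 was 7.25 ± 0.08 in wild type and 4.81 ± 0.00 in knockout (SD, n = 2 each), and 103 passed the test as lower, or 104 with 75th percentile scaling. Of 696 probes first detected at P21 in wild type, 589 (84.6%) were detected on both P60 wild-type arrays, and 294 (42.2%), 353 (50.7%) and 333 (47.8%) on both knockout arrays at P21, P30 and P60. The probes first detected at P21 were thus partly detected in knockout. Those first detected at P30 were mostly not detected in knockout at P30 or P60. The 696 were lower in knockout too, with a mean at P60 of 8.92 ± 0.01 in wild type and 6.24 ± 0.03 in knockout (SD, n = 2 each). They were brighter in wild type than the 130, so a like fall leaves more of them detected. No test compared the 2 groups of probes.

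A group of 778 probes was detected on both wild-type arrays at P15 and on neither at P30. At P60, 24 (3.08%) were detected on both wild-type arrays and 171 (22.0%) on both knockout arrays. By the test 123 (15.8%) were higher in knockout and 8 lower, a smaller share than the 4060 of all 13491 tested probes or the 39.4% of those detected at both P15 and P30 in wild type, and with 75th percentile scaling 57 and 8. The shares are not a like comparison, because these probes lay near background. At P60 their mean log2 signal was 4.89 in wild type and 5.22 in knockout. For probes detected at both P15 and P30 it was 8.67 and 8.94.

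In P60 knockout 100 probes were higher than wild type at every one of the 4 ages (limma, the largest of 4 p-values adjusted over 13491 probes), and 7 were lower. The counts were 70 and 1 with 75th percentile scaling, and 165 and 7 without background correction. These 100 were 2.46% of the 4060 probes higher at P60. They were chosen for lying above every wild-type age, so that trait is not a separate result. The median log2 shift of 0.315 between genotypes at P60 was not subtracted. ILMN_1212921 was between 4.56 and 5.07 in the 4 wild-type groups and 4.57, 7.88, 10.93 and 11.02 in knockout from P15 to P60. ILMN_2668289 was between 4.57 and 5.03 in wild type and 4.82, 5.75, 7.89 and 8.45 in knockout.

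Replicates at P21 in both genotypes and at P30 in wild type were spread along PC1. The P21 knockout arrays lay at -15.1 and -44.3 on PC1, the P21 wild-type arrays at 38.3 and 12.9, and the P30 wild-type arrays at 88.8 and 120. The P30 knockout arrays were closer, at 3.35 and -4.31. In both genotypes at P21 replicate 1 lay further along PC1 than replicate 2, and the differences between replicates had a correlation of 0.488 across probes.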
